A study of Danio rerio with 10 samples.

How the data were processed

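Zebrafish embryos of the AB strain were compared after local loss of ntla, the Brachyury homolog required for notochord formation. One group of zygotes (ntla_cMO) received a caged morpholino against ntla together with caged fluorescein dextran, and the other (control) received the caged dextran alone. A morpholino is an antisense oligomer that blocks splicing or translation of the RNA it binds, and a caged one acts only after light removes its blocking group. The shield, the dorsal organiser, was irradiated over a circle 100 µm wide with 360 nm light at 6 hours post-fertilization (hpf). Fluorescent cells were sorted at 9 hpf, about 8000 per sample from 25 to 30 embryos. Per the labels' protocols, the RNA was amplified as cDNA over 22 PCR cycles to an average length of 400 bp. The Cy3-labelled cDNA of each sample was hybridised to a 1-colour NimbleGen expression array. There were 5 biological replicates of each group, 10 arrays in all. The labels describe the controls as paired with the replicates.

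Per the file headers, raw probe intensities were extracted with NimbleScan version 2.4.31. The raw files deposited by the authors hold linear intensity per probe, with no normalization. Each array had 389307 probes, of which 4307 were random control probes and 385000 belonged to 37157 targets, with at most 12 probes per target. The authors also deposited intensity per target, background corrected, quantile normalized and summarised by RMA at the array maker, per the series' design text. The values of the deposited series table were identical to these summaries. A further deposited table held 121 targets with the same values, and how those targets were picked is not given in the sources used here. The design text names fold changes over 2 with p under 0.10 in a moderated test, without saying whether p was adjusted.

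The values reported here were computed from the raw probe intensities. Background was corrected with limma (version 3.58.1 in R 4.3.3) by normexp with an offset of 50. Arrays were quantile normalized, and the log2 probe values of each target were combined by median polish. Background per array was the 95th percentile of the random probes. Targets above it on at least 5 of the 10 arrays were kept, 24172 targets or 65.1% of the total. The groups were compared with limma's lmFit and eBayes without a block, with Benjamini-Hochberg adjustment over the kept targets and a threshold of 0.05. The study's thresholds were applied as fold over 2 and unadjusted p under 0.10, with the count at an adjusted p under 0.10 beside it. The unadjusted form is called the study's rule below, though the study may have adjusted p. The threshold of signal over background limits the precision for dim targets. Where a target was not above background on any array of a group, its fold is given as "at least", with the dim group's arrays set to the higher of their background level and the measured value. Otherwise the number of arrays limits the precision. Other software was jsonlite 2.0.0, matrixStats 1.5.0, the data.table package (version 1.17.8), and Python 3.11.15 with matplotlib 3.10.9 for the plots.

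Gene symbols were taken from a RefSeq table (assembly GRCz12tu), used only for names and matched on accessions without versions. Of 3055 targets with RefSeq transcript accessions, 2663 matched, 7.17% of all targets, and 392 did not. Of the matched targets, 1816 were kept, with 1810 distinct symbols. The other 34102 targets have Ensembl, Vega, expressed-sequence or assembly identifiers that the tables used here do not pair with a symbol. All counts of named genes and list members therefore cover a small part of the array. The level of ntla (tbxta) itself was not analysed here. A morpholino need not lower the level of its target RNA.

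The rule for named genes was fixed before the data were examined. It took tbxta, the 15 genes with the largest change in each direction among those passing the adjusted threshold, and, where fewer than 10 passed, genes past the study's rule. It also took up to 4 members with the smallest p from each of 22 gene lists, and up to 10 genes of the authors' table. Genes that passed with the replicate block and not without it are named in addition, chosen after their values were seen. The lists covered the tissues of the late gastrula, signalling pathways and general cell functions. Lists with at least 2 measured members were tested with camera at a preset inter-gene correlation of 0.01, using for each gene the target with the highest mean, and again with an estimated correlation.

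Whether replicate numbers pair the samples was checked from the deviations of each array from its group mean. The correlations of the same-numbered arrays were 0.386, 0.722, 0.217, 0.332 and 0.191 for replicates 1 to 5, and arrays with different numbers had a mean correlation of -0.0927. Centring each group ties that mean to the pairs' own, so it is no independent comparison. The best match had the same number in both directions for replicates 1, 2 and 4. However, ntla_cMO 3 matched control 1 best, control 3 matched ntla_cMO 4 best, and control 5 matched ntla_cMO 2 best. With the labels' description of paired controls, the numbers were taken to pair the samples, and values with the replicate as a block are given where they change a call or a count. The arrays were extracted on 2 days, with 9 arrays on the first day and ntla_cMO 4 alone on the second. Values within the first day are therefore those without ntla_cMO 4.

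The fit was tested on simulated data for the comparison of ntla_cMO with control, with 24172 targets of which 200 were changed. At a fold of 1.5 it recovered 0% of the changed targets, at a fold of 2 it recovered 78.5% with 4 false calls, and at a fold of 4 it recovered 100% with 14 false calls. With the replicate block the recovered shares were 0%, 69.5% and 100%. The simulated noise was independent between arrays, with no pair effect and no component shared by arrays. The recovered shares and false calls, with or without the block, may therefore not hold for the real arrays. Alternatives to the background correction, the normalization, the summary over probes, the filter, the block, the array weights, the variance prior, the extraction day and each single array were run, and their effects are given in the closing section. In counts of settings, the deposited RMA values and the identical series table count separately. So do the extraction day as a block and the identical fit without ntla_cMO 4. Probes at the scanner maximum of 65535 were kept.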

Results

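Gene expression was measured in cells of the irradiated shield of zebrafish embryos, in 5 samples with caged ntla morpholino (ntla_cMO) and 5 control samples. Per the labels, irradiated control cells go on to form notochord and floor plate, and cells that lost ntla form floor plate alone. The comparison asks which transcripts differ at 9 hpf after the ntla morpholino is released. The control cells received no morpholino, so loss of ntla cannot be told apart from other effects of a released morpholino. Raw probe intensity had a median between 492 and 919 per array. This was 1.74 to 4.86 times the median of the random control probes of the same array. Between 20158 and 28253 of the 37157 targets were above background on an array, and 8 to 160 probes per array were at the scanner maximum. Correlations between arrays over the kept targets lay between 0.861 and 0.980. The ntla (tbxta) transcript was not analysed here.

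A set of transcripts was lower in ntla_cMO cells than in control cells, and without the replicate block nearly all calls were on the lower side. In ntla_cMO cells 116 targets fell and 1 rose (limma, adjusted p under 0.05, n = 5 per group), among 24172 targets tested. At an unadjusted p under 0.05 there were 3669 targets, 1201 higher and 2468 lower, and with the replicate block 7408, 3131 higher and 4277 lower. The 8 called targets with a gene symbol all fell. They were rgmb, twist2, smyd1b, tspan4b, wnt3a, adora2ab, camk2n2 and hjv. All 116 fell in 5 of 5 replicate pairs, which their choice by low p on these arrays favours, and were above background on all 5 control arrays. Of these, 104 were measured in both groups, here meaning above background on at least 1 ntla_cMO array. The 104 had a median log2 fold change of -1.04 and a range from -2.13 to -0.64, and 59 of them fell over 2-fold. Only 85 were above background on all 10 arrays, with a median of -1.04 too. The other 12 of the 116 were not above background on any ntla_cMO array, with folds of at least 1.01 to at least 1.85. With these at their bounds, the median over the 116 was -1.01. The median log2 fold change of all kept targets was -0.10, and relative to it the median of the 104 targets measured in both groups was -0.94. Median scaling of the arrays moved the median of all targets to -0.29, and relative to that the same 104 targets had a median of -1.01.

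With the replicate block, 229 targets were lower and 64 higher, and 116 of the 117 calls were shared with the same sign. The blocked counts were 63 lower and 5 higher without replicate 1, 52 lower and 1 higher without replicate 2, 3790 lower and 3621 higher without replicate 3, 68 lower and 3 higher without replicate 4, and 100 lower and 12 higher without replicate 5. The arrays control 2 and control 5 stood apart from the others on the first principal component, which held 54.6% of the variance, and without both arrays 36 targets were lower and 0 higher. Without 1 array, the count of lower targets was 64 without ntla_cMO 1, 68 without ntla_cMO 3, 76 without ntla_cMO 4 (the first extraction day alone), 68 without ntla_cMO 5, 71 without control 2, 57 without control 4 and 65 without control 5. The single higher call was lost without any of ntla_cMO 1, 2, 3, 4 or 5 and control 1, 2, 4 or 5, and 6 targets were higher without control 3. Without both control 2 and control 5, all 116 targets still had a negative log2 fold change, and the 104 measured in both groups had a median of -0.98, against -1.04 over all arrays. The 116 were chosen on a set that holds these same arrays, so this is no independent evidence of direction.

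**Figure D1:**
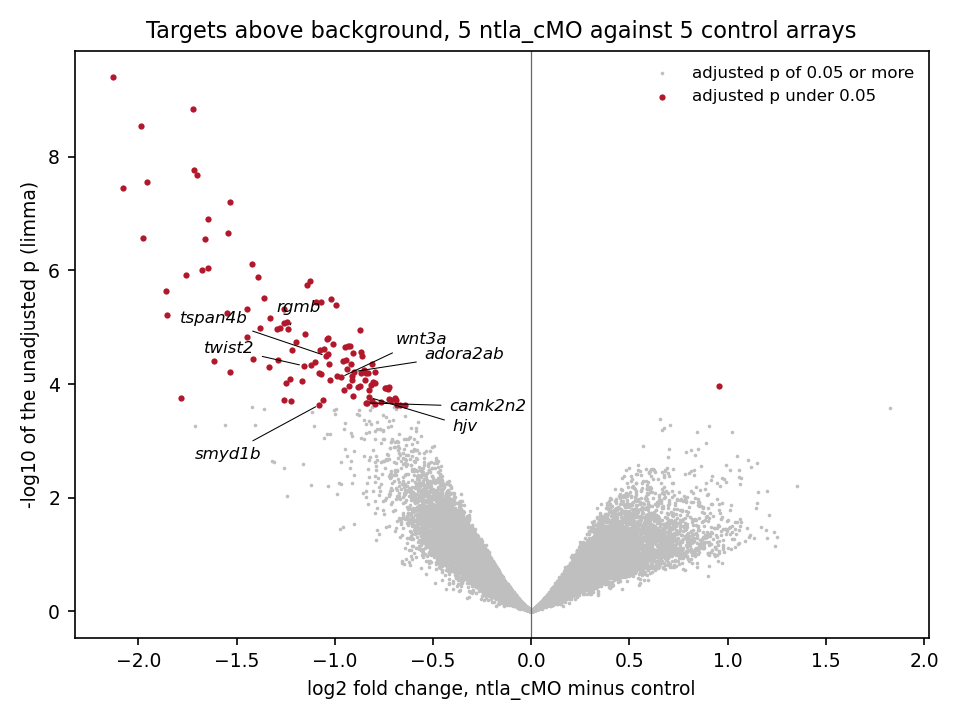
Log2 fold change (ntla_cMO minus control, x axis) against -log10 of the unadjusted limma p (y axis) for 24172 targets, 1 point each, with targets at an adjusted p under 0.05 in red and the 8 called genes with a symbol labelled. The red points comprise 116 on the lower side and 1 on the higher side.

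The 8 named genes that fell included 2 members of the repulsive guidance molecule family, which act as co-receptors of bone morphogenetic proteins. The first, rgmb, had a mean log2 intensity of 11.10 ± 0.40 (SD, n = 5) in control and 9.87 ± 0.09 in ntla_cMO cells, a log2 fold change of -1.24 ± 0.18 (SE; limma adjusted p = 0.00714), or 2.35-fold lower. The second, hjv (hemojuvelin), fell from 9.38 ± 0.19 to 8.55 ± 0.26, a log2 fold change of -0.82 ± 0.16 (limma adjusted p = 0.0414), and was above background on 3 of 5 ntla_cMO arrays. The transcription factor twist2, of the basic helix-loop-helix class, fell from 13.14 ± 0.17 to 11.98 ± 0.43, a log2 fold change of -1.16 ± 0.20 (limma adjusted p = 0.0178). The secreted signal wnt3a, which acts in posterior growth, fell from 10.26 ± 0.24 to 9.29 ± 0.29, a log2 fold change of -0.97 ± 0.17 (limma adjusted p = 0.0233). These genes fell in 5 of 5 pairs.

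The other 4 were smyd1b, a methyltransferase of muscle fibre assembly, tspan4b, a membrane protein of the tetraspanin family, adora2ab, an adenosine receptor, and camk2n2, an inhibitor of calcium/calmodulin-dependent kinase II. The log2 fold change was -1.08 ± 0.22 for smyd1b (limma adjusted p = 0.0488) and -1.04 ± 0.17 for tspan4b (limma adjusted p = 0.0145), which was above background on 3 of 5 ntla_cMO arrays. The log2 fold change was -0.84 ± 0.17 for camk2n2 (limma adjusted p = 0.0467), which was above background on 1 of 5 ntla_cMO arrays. Since adora2ab was not above background on any ntla_cMO array, its level was at least 1.18-fold lower (limma adjusted p = 0.0207). With the replicate block the call of smyd1b was lost (adjusted p = 0.0544, and from 0.0255 to 0.154 over all settings), and the other 7 were kept. Only rgmb and tspan4b kept their calls without each single array. The call of twist2 was lost without ntla_cMO 5, control 4 or control 5, and that of wnt3a without ntla_cMO 1, 4 or 5 or control 4 or 5. The other calls were kept only without 1 or 2 of the arrays. These were control 5 for smyd1b, control 2 for camk2n2, ntla_cMO 3 for hjv, and control 3 or control 4 for adora2ab. Calls were also lost with other processing. These were wnt3a (adjusted p = 0.102), adora2ab (0.0706) and smyd1b (0.154) with cyclic loess, adora2ab (0.0743) and camk2n2 (0.0781) with median scaling, and camk2n2 (0.0939), hjv (0.0649) and smyd1b (0.0612) without background correction. The call of smyd1b was also lost without the filter and with a trended, robust variance prior. Without both control 2 and control 5, and with the first principal component as a covariate, all of the 8 calls but rgmb were lost. Without both arrays the log2 fold changes of smyd1b (-1.23), wnt3a (-1.07) and camk2n2 (-0.95) were larger in size than over all arrays. Those of twist2 (-1.07), tspan4b (-0.84) and hjv (-0.81) were smaller, as was that of adora2ab. The highest adjusted p over all settings was 0.0467 for rgmb, 0.0960 for tspan4b, 0.149 for twist2, 0.102 for wnt3a, 0.146 for adora2ab, 0.148 for camk2n2 and 0.211 for hjv.

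**Figure D2:**
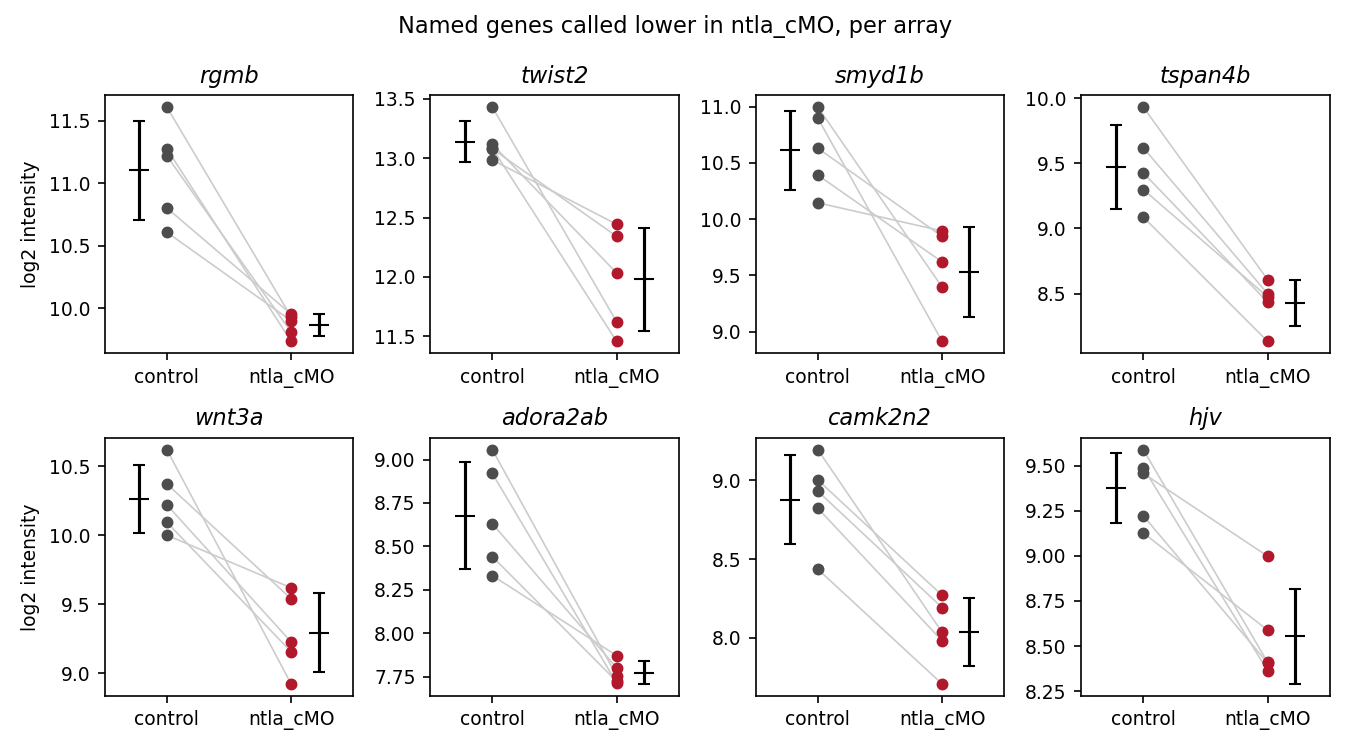
Normalized log2 intensity (y axis) of the 8 called genes with a symbol on each of the 10 arrays, with control in grey and ntla_cMO in red, lines joining arrays of the same replicate number, and the horizontal marks and bars beside the points giving the mean and SD. Each gene was lower in ntla_cMO in 5 of 5 pairs, and rgmb lay between a mean of 11.10 in control and 9.87 in ntla_cMO.

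Among called targets measured in both groups, the largest decrease belonged to a target with no symbol in the tables used here. OTTDART00000023258 fell from 11.50 ± 0.15 to 9.38 ± 0.13 log2 units, a 4.37-fold decrease (limma adjusted p = 9.66e-06). Another target without a symbol, OTTDART00000018441, was not above background on any ntla_cMO array and was at least 1.67-fold lower (limma adjusted p = 1.73e-05). The single target that rose, TC267504, had a log2 fold change of 0.96 ± 0.18 (limma adjusted p = 0.0289) and was higher in 5 of 5 pairs. Its call was lost with median scaling, at a log2 fold change of 0.76 (adjusted p = 0.124), and with cyclic loess, at 1.16 (0.0567).

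A further 10 named genes passed with the replicate block and not without it. All but rapgef5b, a gene of the authors' table, were chosen after their values were seen. The lysophosphatidic acid receptor lpar1 had a log2 fold change of -0.89 ± 0.14 (blocked SE; blocked adjusted p = 0.0169, limma), against an adjusted p of 0.0621 without the block. The sialyltransferase st3gal8 had -0.73 ± 0.14 (blocked adjusted p = 0.0427), the adhesion molecule kirrel3l had -0.72 ± 0.13 (0.0265), the selenoprotein selenon had -0.71 ± 0.12 (0.0264), and the ubiquitin ligase wwp2 had -0.70 ± 0.12 (0.0285). The RNA-binding protein qkia had -0.69 ± 0.14 (0.0458) and the pseudokinase trib3 had -0.65 ± 0.13 (0.0452). The exchange factor rapgef5b, not above background on any ntla_cMO array, was at least 1.12-fold lower (0.0442). The higher ones were trip10b, an adaptor of the F-BAR class, at 0.78 ± 0.16 (0.0442), and the gonadotropin subunit lhb at 0.75 ± 0.14 (0.0333). On control 2 and control 5 trip10b had a log2 intensity of 9.40 and 9.68, against 10.18 to 10.70 on the other controls. The dim lhb was above background on 3 of 5 control and 4 of 5 ntla_cMO arrays. Over all settings their lowest log2 fold changes were 0.33 for trip10b and 0.44 for lhb. For the 10 genes, the adjusted p without the block lay between 0.0512 for wwp2 and 0.327 for selenon. Without ntla_cMO 2, lpar1 passed without a block, and wwp2 did so without control 3. Of all settings, wwp2 passed in 7, rapgef5b in 4, lpar1 and kirrel3l in 3 each, and the other 6 in 1, the block. The 4 of rapgef5b include the deposited RMA values and the identical series table. The adjusted p over all settings lay between 0.0169 for lpar1 and 1.00 for selenon.

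By fold over 2 and unadjusted p under 0.10, the form called the study's rule here, 85 targets were lower and 51 higher. With p adjusted 75 were lower and 1 higher. With the replicate block and p adjusted, 85 were lower and 50 higher. The split between directions moved with the processing. Median scaling of the arrays gave 171 lower and 9 higher, and cyclic loess gave 62 lower and 260 higher. The deposited RMA values, quantile normalized like the values here, gave 161 lower and 184 higher. The count of higher targets lay between 12 without control 2 and 393 without control 3. It was 197 without ntla_cMO 2, 24 without ntla_cMO 4, 175 without control 1, 79 without control 4 and 14 without control 5. No further named gene met this rule, so none was added to the 8.

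The authors' deposited table of 121 targets held 116 that were lower and 5 that were higher in ntla_cMO in the authors' values, and 9 had a symbol. These targets were chosen on the same arrays and are no independent evidence of direction. All 121 passed fold over 2 and adjusted p under 0.10 in a limma fit to the authors' values, with folds of 2.00 or more and adjusted p up to 0.0836, among 130 targets of the array that did so. With unadjusted p under 0.10 in that fit, 224 targets were lower and 203 higher at that fold. The deposited table therefore goes with an adjusted p. All 121 had the same sign in the values computed here. The filter kept 107 of them, of which 92 were called without and 105 with the replicate block. The 9 with a symbol were rgmb, twist2, smyd1b, tspan4b, wnt3a, adora2ab, camk2n2, hjv and rapgef5b. In the authors' values rgmb was 2.59-fold lower. Across targets, which are not independent replicates, the log2 fold changes computed here and from the authors' values had a correlation of 0.981.

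Notochord and floor plate genes are the readout named by the labels, and few of them had a symbol here. Of 20 notochord genes 3 were measured, and none passed. The laminin chains lama1 and lamb1a, parts of the basement membrane around the notochord, had log2 fold changes of -0.25 ± 0.15 (limma adjusted p = 0.347) and -0.20 ± 0.17 (adjusted p = 0.446). The caveolar coat gene cav1 had 2 targets that differed in sign, at 0.11 ± 0.26 and -0.22 ± 0.21. The list had a median of -0.20 (camera adjusted p = 0.733), which was -0.59 with median scaling, -0.09 with cyclic loess, and -0.13 without ntla_cMO 1 or without control 2. Of 14 floor plate genes only foxj1a, a regulator of motile cilia, was measured, at 0.27 ± 0.15 (limma adjusted p = 0.346), higher in 3 of 5 pairs. A single gene gives no list test.

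The tailbud and posterior growth list had the lowest median, -0.71 over its 2 measured members wnt3a and cdx1a. With no filter, its 3 members on the array had a median of -0.44 (camera adjusted p = 0.0860). With the filter the list did not pass (camera p = 0.00490, adjusted p = 0.0588 over 12 lists tested), and its p was 0.0621 with an estimated correlation, adjusted p = 0.498. The list passed in 11 of 27 settings, among them without ntla_cMO 4 (adjusted p = 0.0320), without control 2 (0.00330) and without control 5 (0.0279). The 11 also count the extraction day as a block, which is the same fit as without ntla_cMO 4. Over all settings its adjusted p lay between 0.000156 and 0.498. wnt3a fell, and cdx1a, a homeobox gene of the posterior body, had a log2 fold change of -0.44 ± 0.18 (limma adjusted p = 0.327). Both passed when adjusted over the list alone, and of the 38 genes measured over all lists only wnt3a passed when adjusted over those 38 (limma adjusted p = 0.00289). The planar cell polarity and cell adhesion list had 4 members, all with negative estimates, and a median of -0.35 (camera adjusted p = 0.0838, adjusted p = 0.498 with an estimated correlation). Its median was -0.71 with median scaling and -0.21 with cyclic loess. This list passed in 5 of 27 settings. These were no background correction (camera adjusted p = 0.0455), the mean over probes (0.0375), no filter (0.0351), without control 5 (0.0409) and without both control 2 and control 5 (0.0317). Its adjusted p over all settings lay between 0.0317 and 0.498. The hyaluronan synthase has2 had -0.78 ± 0.24 (limma adjusted p = 0.307), the polarity gene vangl2 -0.37 ± 0.18, the cadherin celsr2 -0.33 ± 0.13 and the integrin chain itgb1b -0.25 ± 0.14. Of the 4, 2 passed when adjusted over the list alone.

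Mesodermal and ectodermal groups had small shifts that did not pass. In presomitic and paraxial mesoderm, aplnrb, an apelin receptor, had -0.41 ± 0.18 and ripply1, a regulator of somite formation, -0.30 ± 0.24, with a list median of -0.35 (camera adjusted p = 0.348). The 4 neural ectoderm genes had a median of -0.33 (camera adjusted p = 0.283), with her3, a Hairy-related repressor, at -0.74 ± 0.25, the SoxB1 gene sox19b at -0.49 ± 0.18, the forebrain gene fezf2 at -0.17 ± 0.15 and gbx1 at -0.05 ± 0.18. Of these, 2 passed when adjusted over the list alone. The neural ectoderm median was -0.63 with median scaling and -0.13 with cyclic loess. The presomitic and paraxial mesoderm median was -0.58 and -0.14 in the same order. The ventrolateral mesoderm, blood and heart genes hhex, spi1b and osr1 had 0.32 ± 0.17, 0.04 ± 0.15 and 0.00046 ± 0.28, with a median of 0.04 (camera adjusted p = 0.296). The single measured genes of epidermis (gata3, 0.11 ± 0.24) and prechordal plate (prdm1a, 0.29 ± 0.19) did not pass. The direction of gata3, prdm1a, osr1, gbx1, spi1b and ripply1 depended on the setting. Among the scalings, median scaling turned gata3, prdm1a and osr1 negative, and cyclic loess turned gbx1 positive and spi1b negative. The sign of osr1 was also negative with the deposited RMA values and without background correction, and that of gbx1 positive with array weights. Without both control 2 and control 5, and with the first principal component as a covariate, ripply1 and gbx1 were positive and spi1b negative. Leaving out single arrays turned osr1, gata3, gbx1 and spi1b as well.

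Among pathways, the hedgehog response genes gli3, boc and gli2b had 0.27 ± 0.16, -0.27 ± 0.18 and -0.09 ± 0.13. Their median was -0.09, while camera put the list on the higher side (adjusted p = 0.733), and with cyclic loess the median was 0.05, since gli2b turned positive, as it also did with the first principal component as a covariate. The Notch pathway genes her12 and mib1 had -0.38 ± 0.23 and -0.25 ± 0.18 (median -0.31, camera adjusted p = 0.401), and the FGF receptor fgfr2 had -0.38 ± 0.17, which passed over its own list of 1 measured gene only. The motile cilia genes rfx3, foxj1b and foxj1a had -0.29 ± 0.15, 0.25 ± 0.18 and 0.27 ± 0.15 (median 0.25, camera adjusted p = 0.401), and with median scaling foxj1b turned negative and the median was -0.06. In the cell cycle list, mcm5, of the replicative helicase, had -0.46 ± 0.17 and ccna2 -0.24 ± 0.16 (median -0.35, camera adjusted p = 0.296), and 1 of the 2 passed when adjusted over the list alone. The extracellular matrix and secretion list had 4 members (median -0.26, camera adjusted p = 0.237), of which plod2, a lysyl hydroxylase of collagen, had -0.64 ± 0.22 on one target and -0.31 ± 0.16 on its other target. That list's creb3l2 had -0.26 ± 0.15, and 1 of the 4 passed when adjusted over the list alone. The 5 ribosomal protein genes had a median of -0.16 (camera adjusted p = 0.513), with rpl27a at -0.28 ± 0.15, rps6 at -0.20 ± 0.14, rps20 at -0.16 ± 0.15 and rpl37 at -0.09 ± 0.18, and rps20 turned positive with cyclic loess. Without both control 2 and control 5, and with the first principal component as a covariate, rpl37 was positive. None of the 12 lists tested passed after adjustment, and 2 had an unadjusted camera p under 0.05. Endoderm and dorsal forerunner cells, germ cells, yolk syncytial layer, p53 response, dissociation and heat shock stress, and Nodal and BMP pathways had 0 measured members and were not analysed here.

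**Figure D3:**
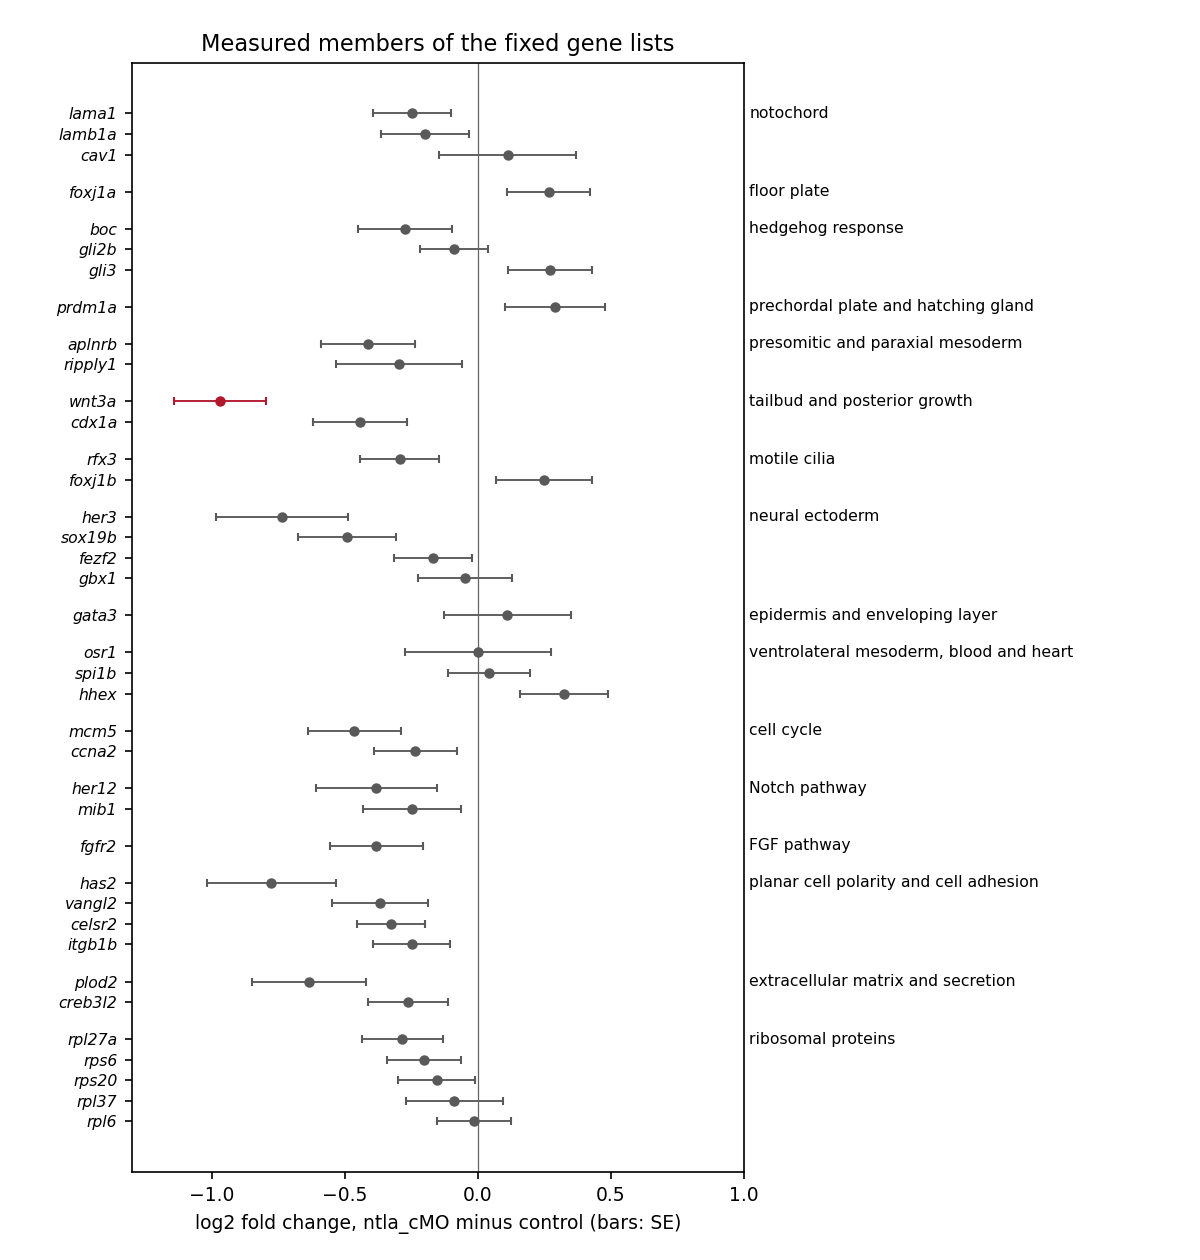
Log2 fold change (ntla_cMO minus control, x axis; bars give the SE) of the 38 measured members of the fixed gene lists, 1 target per gene and grouped by the first list that holds the gene, with the gene passing an adjusted p under 0.05 in red. Only wnt3a, at -0.97, is red.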

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

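In 5 of 124 groups of 5 arrays, 1 array lay far from the other 4 by Dixon's test, where chance gives 6.2. These were rfx3 on ntla_cMO 3 (log2 intensity 11.83, the others between 11.26 and 11.40), plod2 on ntla_cMO 1 (12.55, the others between 13.38 and 13.63), rapgef5b on ntla_cMO 2 (8.19, the others between 7.91 and 7.98) and wwp2 on ntla_cMO 3 (10.68, the others between 10.96 and 11.01). The raw median intensity was 919 on ntla_cMO 4, the only array of the second extraction day, and between 636 and 677 on the other ntla_cMO arrays.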

How the results depend on the processing

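The settings without both control 2 and control 5, with the first principal component as a covariate, with the replicate block and without each replicate in turn, and with the deposited RMA values and the replicate block were chosen after seeing the data. No called value changed sign. All 117 called targets kept their sign in every setting that tested them, and the notochord and floor plate values stayed short of the threshold throughout. The 117 were chosen on the same arrays, so their kept sign is no independent evidence of direction. Of the values per named gene or list, 47 stayed on their side of the threshold in all settings. The number of arrays, and for dim targets the signal over background, limit what can be called.

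The adjusted counts were 2 higher with the deposited RMA values and the identical series table, 0 higher with median scaling, 0 higher and 67 lower with cyclic loess, 2 higher with the mean over probes, 8 higher and 183 lower with array weights, and 76 lower with the extraction day as a block. The replicate block gave 64 higher and 229 lower, and with the deposited RMA values and the block 64 and 222. Apart from these counts, those at an unadjusted p under 0.05 or an adjusted p under 0.10 with a fold over 2, the named calls it gained and that of smyd1b, the block changed no other call. Under the block, the counts were 5 higher and 63 lower without replicate 1, 52 lower without replicate 2, 3621 higher and 3790 lower without replicate 3, 3 and 68 without replicate 4, and 12 higher without replicate 5. Without both control 2 and control 5 they were 0 and 36, and with the first principal component as a covariate 46 were lower. Leaving out single arrays gave 0 to 6 higher and 57 to 147 lower. Fewer arrays can lower the counts by construction, yet the counts rose without control 3 or replicate 3. On the first principal component replicate 3 was the only pair higher in ntla_cMO. Its difference was 9.17, against -89.8 to -26.7 in the other pairs. The cause of the changed counts was not tested.

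By the study's rule, the counts of higher and lower targets were 184 and 161 with the deposited values and the series table, 25 and 51 without background correction, and 9 and 171 with median scaling. Higher targets numbered 260 with cyclic loess, 31 with the mean over probes, 88 with array weights, 24 with the extraction day as a block, 6 without both control 2 and control 5, and 10 with the component as a covariate. Under the block they numbered 162, 13, 374 and 14 without replicates 1, 2, 3 and 5, and with the deposited values 202, with 161 lower. Leaving out single arrays gave 12 to 393 higher and 76 to 104 lower. The cause was not tested.

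Lists past the adjusted threshold numbered 0 as reported, 2 without background correction or with the mean over probes, 3 without both control 2 and control 5, and 0 to 2 without single arrays. They numbered 1 with cyclic loess, no filter, the filter on all 10 arrays, array weights, the extraction day as a block or the component as a covariate. The cause was not tested.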

Other observations

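The families of gene symbols, the values and the test without both control 2 and control 5, and the comparison of the first principal component with the ntla morpholino were chosen after the data were seen, as was the comparison of the component within pairs.

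Among families of symbols sharing a prefix, 12 had at least 8 measured genes. The protocadherins, cell adhesion proteins encoded in clusters, had higher estimates in ntla_cMO for 10 of 10 genes, with a median log2 fold change of 0.45 (camera adjusted p = 7.25e-05 over the 12 families, adjusted p = 0.625 with an estimated correlation). No single member passed. The largest estimates were 0.71 ± 0.34 (SE) for pcdh1g1 and 0.59 ± 0.24 for pcdh2g29 (limma adjusted p = 0.327 for both). Genes of 1 cluster can be close in sequence, so the 10 may not be independent, and whether their probes share transcripts was not tested. The estimates were positive for all 10 under median scaling and cyclic loess too, with medians of 0.45 and 0.36. Without control 2 the median was 0.25, and without both control 2 and control 5 it was 0.07, with 8 of 10 genes higher.

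Nearly all called targets were lower in ntla_cMO. Under both median scaling and cyclic loess 100% of the calls were lower. However, 97 of the 114 calls with median scaling and 66 of the 67 with cyclic loess were already calls of the full fit. Median scaling also moved the median of all targets to -0.29. These shares could hardly fall, and do not decide whether the normalization between arrays is the source. They cover the adjusted calls alone. By the study's rule cyclic loess gave 260 higher and 62 lower, and median scaling 9 higher and 171 lower. Without control 2 and control 5 the calls were 36 lower and 0 higher, again 100% lower. All 36 were among the calls of the full fit, nearly all of them lower. The share could therefore hardly fall, and this does not decide whether control 2 and control 5 are the source. With the replicate block 64 calls were higher, and the lower calls may follow from the morpholino or from a different makeup of the sorted cells, and these were not tested against each other.

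Among splits that ignore the pairing, few gave as many calls as the 116 lower targets, and more did so for the counts by the study's rule with unadjusted p. The samples were taken as paired, so these splits cannot exclude chance for either. Splits that part the pairs are too few to tell. Of 100 splits of the arrays into 5 and 5, out of 126, 3 gave as many calls in one direction as the 116 and 4 as many as the 1, the real split included, and the highest other count was 3769. A single higher call is no more than the 4 false calls of the simulation at a fold of 2, whose noise was independent between arrays. Chance stays open for that call too. By the study's rule, 10 of the 100 splits gave as many as the 85 lower and 13 as many as the 51 higher, with a highest other count of 697. The split with 3769 higher and 2826 lower set ntla_cMO 1, 3, 4 and 5 and control 3 against the rest. These 5 arrays have the lowest scores on the first principal component, so the split points to a structure of the samples along that component. Among the 16 splits that part all 5 pairs, all fitted without the block too, no split but the real one gave a call, and the highest other count was 0. With the block, 2 of the 16 splits gave as many as the 229 lower and 2 as many as the 64 higher, and the highest other count was 1957, with the labels of replicate 3 exchanged. These 16 splits are too few for a share under 0.05.

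On the first principal component control 2 scored 75.6 and control 5 scored 62.8, against -47.1 to 23.9 for the other 8 arrays. The ntla morpholino stays open as a source. While 2 of the control arrays lay within the range of the ntla_cMO arrays (exact permutation p = 0.103, two-sided, for the difference of the means, -47.7), 4 of 5 pairs were lower in ntla_cMO (exact sign-flip permutation p = 0.125, two-sided, where 5 pairs allow no p under 0.0625). Coverage along the transcripts stays open: the slope of signal on probe position had a Pearson r of 0.546 with the component over 10 arrays (permutation p = 0.105, 0.210 adjusted over 2 relations) and a Spearman rho of 0.503 (p = 0.143, 0.287 adjusted), and r was 0.245 without control 5 and ntla_cMO 1. The spread of raw intensities stays open too, with r = 0.420 (permutation p = 0.231, 0.231 adjusted) and rho = 0.152 (p = 0.685, 0.685 adjusted), and r was -0.196 without control 2 and ntla_cMO 5. Neither relation was clear enough over 10 arrays to decide.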
